A study of Mus musculus with 10 samples.

How the data were processed

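Mouse skeletal muscle macrophages and leukocytes were profiled by droplet single-cell RNA sequencing (10x, 3' chemistry on a NextSeq 500, per the labels). Each of 7 libraries came as a matrix of whole-number UMI counts per gene and cell barcode, not normalised, as deposited by the authors. Cell Ranger 4.0.0 and Seurat are named in the submitters' processing notes without a role, along with the builds mm10 and GRCm38.p5. The barcode and feature lists that go with the matrices were used as deposited. The deposited counts hold barcodes with at least 500 UMIs, and other filters were not given in the sources used here. No column of another study's samples was used. The feature lists held 32287 gene features in the parabiosis library, 47729 in the 18 h pool and 28692 in the other 5. Of the 28692 gene identifiers, 28339 (98.8%) were found in the GENCODE annotation of GRCm38, from which positions were taken. Records of 3 hash tag libraries were not used here, because the tag counts stood in the matrices of the pools themselves.

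Cells were kept with at least 300 genes, at least 500 UMIs and at most 10% mitochondrial UMIs. Doublets were scored with scrublet in scanpy. Its automatic threshold marked too few cells to have worked (0.0504% in the parabiosis library), so the highest scores were removed instead, up to the number expected from loading (0.8% per 1000 cells), together with cells that carried 2 hash tags. This replacement was chosen after the data were seen. Cells with 2 tags scored above other cells with an area under the curve of 0.781, 0.727 and 0.853 in the 3 tagged libraries. A cell was given to the tag with the most UMIs when that tag had at least 2 times the count of the next. In the 18 h pool the tags were sparse, and at least 2 tag UMIs were required, which assigned 34.8% of its cells. That minimum was set after the tag counts were seen, and a minimum of 1 was run as an added alternative. Assignment was uneven between clusters of this pool, as given below, so tagged cells need not represent the sorted ones. Per the labels, tags 1 and 2 of this pool marked muscle 18 h after damage and tags 3 and 4 undamaged muscle. In the other pool tags 1 and 2 marked 8 h and tags 3 and 4 marked 3 h after damage. The labels do not say that the tagged samples of a time came from separate animals, so their p-values measure the spread between samples, which may be technical. The labels map no tag of the parabiosis library to a time, so that library was treated as 1 sample.

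Counts were log-normalised, 2000 variable genes were taken after leaving out the functional gene lists and mitochondrial and ribosomal genes, and 30 principal components and 15 neighbours led to Leiden clusters at resolution 1. The 4 mdx libraries were clustered together without integration, and each wild-type library on its own. Clusters were named from 28 marker lists fixed before the data were examined. A name needed a score of at least 1, at least 3 detected markers, and no majority of another class among the leading genes, where the macrophage and monocyte classes counted as 1 family. So cluster 0 of the 3 h and 8 h pool, with 1145 cells, was named classical monocyte by its score although its 10 leading genes held 0 markers of that class and 1 of Gpnmb/Spp1-like macrophages. The scoring details were refined after the clusters were seen. Class names below are short for cells that looked like that class by its markers. Clusters that failed these rules stayed unnamed and were kept out of the named classes.

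Raw counts were summed per mouse, or per tagged sample, and class. The sums were tested with edgeR's quasi-likelihood test (TMM scaling, filterByExpr, Benjamini-Hochberg adjustment, threshold 0.05). Adjusted p-values below come from this test unless another is named. Resident-like cells were compared with other macrophages and monocytes with the sample as a block. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over lists, then with an estimated correlation. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone. Shares of cells were compared by a two-sided exact permutation test, whose smallest p with 2 against 2 mice is 0.333, and by an edgeR model of cell numbers with the spread shared across 22 classes. Shares of cells with a marker UMI were taken after thinning each cell to 1000 UMIs. Cells with fewer UMIs than the thinning depth were left out wherever cells were thinned. Intervals on single shares are exact Clopper-Pearson 95% intervals, which cover counting error only. A fold against a group without counts was set against a floor of 3 counts over the group.

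Genes named in the text were chosen by a rule fixed at the same time as the marker lists. It took the 10 largest increases and the 10 largest decreases past the threshold, with the groups separated and a mean of at least 20 CPM, leaving out predicted, mitochondrial, ribosomal, antigen receptor, haemoglobin and sex-linked marker genes. It added up to 4 called members of each of 19 functional lists, or up to 2 with the smallest p as values. In the mdx comparisons Csf1r, Csf1, Timd4, Lyve1, Folr2, Cd163, Gpnmb, Spp1, Ccr2 and Ly6c2 were added, and where fewer than 3 genes passed, the 5 with the smallest p were given as values. Space allowed a part of those names in the text, and a few are not reported here.

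Depth ranged from 16787256 to 95285990 UMIs per library. On simulated counts with 200 changed genes, the test recovered 8% of 2-fold and 84% of 4-fold changes in the whole mdx sort, 28% and 89% in mdx macrophages and monocytes, and 23% and 91% in mdx Gpnmb/Spp1-like macrophages. In the macrophages and monocytes of the tagged pools it recovered 76% and 99% between 3 h and 8 h, and 28% and 94% between undamaged muscle and 18 h. Between resident-like and other cells it recovered 67% and 93%. Replicate libraries differed beyond sampling noise, with a chi-square per degree of freedom of 2.23 to 139, a measure that grows with depth. In the whole mdx sort it was 139 and 138 between replicates of a diet and 68.2 between control replicate 1 and inhibitor replicate 1. In the pools it was 14.5 and 21.0 within and 119 between 3 h and 8 h, and 2.23 and 3.93 within and 28.7 between undamaged muscle and 18 h. Alternatives were DESeq2, DESeq2 size factors, a filter of at least 1 count, thinning, stricter cell filters, kept doublets, Leiden resolutions of 0.5 and 2, a replicate block and leaving out each replicate. Software was Python 3.11.15 with scanpy 1.11.5 and leidenalg 0.10.2, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.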

Results

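Macrophages and other leukocytes of mouse skeletal muscle were sequenced in 7 libraries. Dystrophin-deficient mdx males, 1 year old, had received control diet (2 mice) or a diet with 200 mg/kg of the CSF1R inhibitor PLX73086 (2 mice) for 10 months by their own labels, while the treatment protocol speaks of at least 3 weeks. Live CD45+ cells of these mice held 17144394 and 40208500 UMIs under control diet and 16787256 and 29903030 under the inhibitor. The second inhibitor mouse also carried a Pdgfra EGFP allele. Filters left 4405 and 7306 control cells and 5442 and 6290 inhibitor cells, with medians of 2549, 3814, 1892 and 2294 UMIs. A pool of F4/80+ cells from wild-type males (20364251 UMIs) gave 232 and 1155 cells tagged as 18 h after muscle damage and 107 and 203 cells tagged as undamaged. A second pool, sorted to balance TIM4+ and TIM4- cells (95285990 UMIs), gave 2011 and 2085 cells at 3 h and 1955 and 2211 cells at 8 h. A library from the wild-type partner of a GFP and wild-type parabiotic pair (55015624 UMIs, 3743 cells) held GFP+ myeloid cells spiked with TIM4+ GFP- cells. Its labels list 6 h and 2, 4 and 8 days after injury and map no tag to any of these times.

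The first question was which leukocytes long CSF1R inhibition leaves in dystrophic muscle. Resident-like macrophages, named by a marker list with Folr2, Cd163, Lyve1 and Timd4, were nearly missing from the inhibitor mice. Resident-like cells made up 4.16% ± 2.51 under control diet and 0.0184% ± 0.026 under the inhibitor (SD, n = 2 mice each), 270.0-fold (95% counting interval 74.4 to 2235) fewer cells per cell sorted. This loss was not one of Timd4 transcripts. After thinning, these were seen in 0.158% and 0.300% of control and 0.171% and 0.763% of inhibitor macrophages and monocytes. The second inhibitor mouse had 0 of 6290 such cells, which allows a share of up to 0.0477%. With doublets kept resident-like cells were 13.3% ± 8.82 under control diet and 0.548% ± 0.54 under the inhibitor, and at Leiden resolution 0.5 no mdx cluster took this name. T cells, regulatory T cells and NK cells took larger shares. T cells were 3.73% ± 2.14 under control diet and 26.0% ± 18.1 under the inhibitor. Regulatory T cells, which restrain inflammation and aid muscle repair, were 0.612% ± 0.13 under control diet and 4.08% ± 0.779 under the inhibitor. NK cells were 2.11% ± 1.32 under control diet and 11.3% ± 5.34 under the inhibitor. The edgeR model of cell numbers called 6 of 22 classes. Resident-like macrophages fell (log2 fold change -7.74, adjusted p = 1.2e-05), as did nonclassical monocytes (-3.36, adjusted p = 0.0272). T cells (2.80, adjusted p = 0.0288), regulatory T cells (2.74, adjusted p = 0.03), NK cells (2.43, adjusted p = 0.0493) and an unnamed cluster with T cell and macrophage transcripts together (2.90, adjusted p = 0.0288) rose.

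Macrophages and monocytes together were 53.7% ± 11.2 under control diet and 22.4% ± 19.2 under the inhibitor. Macrophages of no special class were 24.1% ± 11.3 under control diet and 5.51% ± 5.46 under the inhibitor (-2.13, adjusted p = 0.0652), and Gpnmb/Spp1-like macrophages, a scar-associated type with lipid-handling genes, were 14.0% ± 1.25 under control diet and 6.32% ± 6.35 under the inhibitor (-1.15, adjusted p = 0.335). Neither passed the model. Classical monocytes, the blood-derived precursors, were 10.5% ± 1.52 under control diet and 10.4% ± 7.27 under the inhibitor of all cells (-0.00, adjusted p = 0.997). The inhibitor mice differed from each other, with 13.2% and 38.8% T cells and 35.9% and 8.82% macrophages and monocytes. Type 2 conventional dendritic cells were 7.88% ± 0.697 under control diet and 2.97% ± 1.82 under the inhibitor (-1.41, adjusted p = 0.237), and plasmacytoid dendritic cells 0.525% ± 0.413 under control diet and 1.66% ± 0.821 under the inhibitor (1.68, adjusted p = 0.179). Clusters 5 (Retnla, Ear2) and 7 (shallow cells) looked like macrophages but stayed unnamed by the rules, which were refined after the data were seen. They held 8.27% ± 0.846 under control diet and 2.77% ± 3.28 under the inhibitor, and 8.34% ± 2.50 under control diet and 1.70% ± 1.31 under the inhibitor, respectively. By the two-sided exact permutation test every class that separated the diets had p = 0.333, the smallest p that 2 against 2 mice allow. Without control replicate 1 or control replicate 2 the model called 1 class, without inhibitor replicate 2 it called 2, and without inhibitor replicate 1 it called 12.

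**Figure D1:**
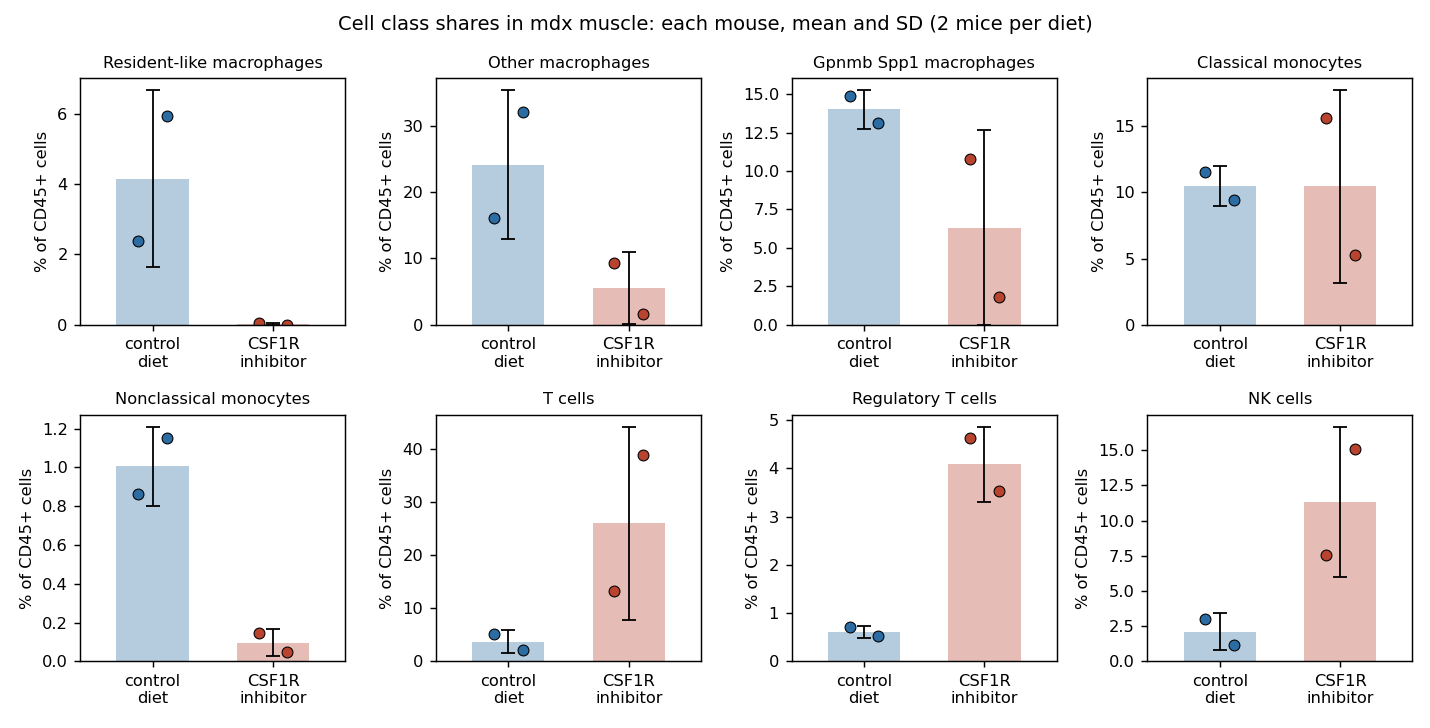
Share of CD45+ cells (%) in 8 cell classes of mdx muscle, 1 panel per class, under control diet and under the CSF1R inhibitor; bars are means of 2 mice, error bars SD, points single mice. Resident-like macrophages averaged 4.16% under control diet and 0.0184% under the inhibitor.

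Marker transcripts were counted cell by cell within macrophages and monocytes, after thinning to 1000 UMIs. Folr2, the folate receptor of resident macrophages, was seen in 7.65% ± 3.07 against 1.10% ± 0.213 of these cells (control against inhibitor, SD, n = 2). Cd163, the haemoglobin scavenger receptor, was seen in 1.95% and 1.85% of control cells and in 0 of 1752 and 0 of 524 inhibitor cells, which allows shares of up to 0.171% and 0.573%. Timd4 was seen in 0.229% ± 0.1 against 0.467% ± 0.419 of macrophages and monocytes. Among classical monocytes it was seen in 0 of 450 and 0 of 616 control cells, which allows shares of up to 0.667% and 0.487%, and in 0.439% and 1.3% of inhibitor cells, while T cell shares were 0.448% in the second control mouse and 0 in the others. Ly6c2, a surface protein of inflammatory monocytes, was seen in 7.54% ± 1.79 against 31.1% ± 11.1 of all macrophages and monocytes. Gpnmb was seen in 33.2% ± 4.59 against 34.2% ± 11.5 and Spp1, or osteopontin, in 31.3% ± 0.964 against 22.6% ± 10.1. In T cells, which should lack Gpnmb and Folr2, Gpnmb shares were 5.81%, 2.69%, 5.19% and 1.38%, and Folr2 shares 0 in 3 mice and 0.122% in the second inhibitor mouse. T cells here include regulatory and gamma delta T cells. Before thinning, the T cell class alone had medians of 1007 and 1849 UMIs in control and 862 and 1794 in inhibitor mice. Most of that class was therefore left out in the first inhibitor mouse. Macrophages and monocytes had medians of 3276, 4014, 2558 and 4681 UMIs before thinning. Ly6c2, which memory T cells also express, was seen in 5.59% ± 0.301 against 30.4% ± 18.6 of T cells, so its difference was not particular to macrophages and monocytes. In B cells it was seen in 3.96% ± 2.88 against 9.64% ± 1.66. Unthinned, the B cell shares overlapped, at 4.79% and 4.48% in control and 3.77% and 14.3% in inhibitor mice. Unthinned Folr2 shares were 20.7% ± 6.90 against 3.64% ± 0.563. Folr2 and Ly6c2 shares separated the diets (two-sided exact permutation p = 0.333, the smallest possible), and 2 against 2 values do so by chance in 33.3% of cases.

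Over all sorted leukocytes, lists of T cell and NK cell genes were higher and resident macrophage markers lower under the inhibitor. The edgeR test called 0 of 12881 genes, with 1714 at an unadjusted p under 0.05, and DESeq2 called 601. The 5 smallest p-values belonged to Sct (4.59 (SE 0.38)), Rgs16 (3.98 (SE 0.40)), Ikzf2 (2.53 (SE 0.28)), Car2 (2.67 (SE 0.30)) and Nt5e (2.83 (SE 0.32)), with adjusted p from 0.129 to 0.137. Csf1r, the inhibitor's target (ENSMUSG00000024621, chromosome 18, 61100598 to 61132149 in GRCm38), had a log2 fold change of -1.02 (SE 0.39). Of the T cell effector and regulatory list 17 of 23 genes rose, adjusted over the list alone, among them Gzmb (3.77 (SE 0.61)), a killer protease, and Pdcd1 (3.10 (SE 0.42)), an inhibitory receptor. Camera gave this list adjusted p = 8.8e-20, and adjusted p = 0.469 with an estimated correlation. The markers of T cells, regulatory T cells and NK cells, 6 of 6, 5 of 5 and 6 of 6, rose with it on the same adjustment. Resident macrophage markers fell in 9 of 10 cases (camera adjusted p = 9.0e-21, and adjusted p = 0.277 with an estimated correlation). Interferon-stimulated genes rose in 12 of 21 cases (camera adjusted p = 1.4e-12, and adjusted p = 0.469 with an estimated correlation), and alternative activation genes fell in 5 of 15 (camera adjusted p = 5.6e-05, and adjusted p = 0.469 with an estimated correlation). None of these list members passed over all genes. Without inhibitor replicate 1 edgeR called 1206 genes, without inhibitor replicate 2 it called 68, and without control replicate 1 or control replicate 2 it called 0.

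In summed macrophages and monocytes a neutrophil-attracting chemokine was higher and a scavenger receptor nearly absent under the inhibitor. The sums held 8932899 and 23500515 UMIs under control diet and 7148967 and 3631791 under the inhibitor. Cxcl3 (ENSMUSG00000029379, chromosome 5, 90786103 to 90789600) rose from 1.38 ± 0.582 to 32.9 ± 5.91 CPM (SD, n = 2), a log2 fold change of 4.45 (SE 0.34) with adjusted p = 0.0108. Cd163 (ENSMUSG00000008845, chromosome 6, 124304656 to 124330527) fell from 14.7 ± 3.18 to 0.283 ± 0.0217 CPM, 56.6-fold (95% counting interval 19.3 to 275) lower, with adjusted p = 0.0122. These were the 2 genes called among 11036. The next smallest p-values belonged to Traf1 (1.98 (SE 0.22)), an adaptor of TNF receptors, Ctsk (2.22 (SE 0.27)), the collagen-degrading cathepsin K, and Mmp14 (1.75 (SE 0.22)), a membrane-bound collagenase, each with adjusted p = 0.0571. Folr2 had -2.78 (SE 0.38), Ly6c2 2.31 (SE 0.40), Csf1r -0.26 (SE 0.28), Csf1 1.32 (SE 0.40), Gpnmb 0.58 (SE 0.32), Spp1 -0.52 (SE 0.36), Ccr2 0.10 (SE 0.26) and Timd4 1.61 (SE 0.68), none of them called. Lyve1 had 211 UMIs in control and 1 in inhibitor cells, 70.1-fold (95% counting interval 12.5 to 2783) lower for its depth.

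By list, more genes of these cells were called within the lists than over all genes. Of 18 inflammatory cytokines, 1 rose over all genes and 8 rose and 1 fell adjusted over the list alone (camera adjusted p = 3.8e-14, and adjusted p = 0.205 with an estimated correlation). Interferon-stimulated genes, the antiviral response set, rose in 15 of 21 cases on the list's own adjustment and in 0 over all genes (camera adjusted p = 5.0e-23, and adjusted p = 0.284 with an estimated correlation). Alternative activation genes, the tissue-repair set, fell in 7 of 15 (camera adjusted p = 1.3e-08, and adjusted p = 0.205 with an estimated correlation). NRF2 antioxidant genes rose in 4 of 14 (camera adjusted p = 1.7e-05, and adjusted p = 0.284 with an estimated correlation) and matrix genes in 3 of 15 (camera adjusted p = 0.0022, and adjusted p = 0.284 with an estimated correlation). Growth factors fell in 4 of 13 (camera adjusted p = 0.00494, and adjusted p = 0.359 with an estimated correlation). Transcripts of other cells moved alongside these lists. All 6 T cell markers rose on the list's own adjustment (median log2 fold change 3.34, camera adjusted p = 1.4e-17, and adjusted p = 0.229 with an estimated correlation), as did 11 of 16 T cell effector genes and 4 of 6 classical monocyte markers. Resident markers fell in 8 of 10. The count of called genes was small and moved with single mice. It was 189 and 66 without control replicates 1 and 2, and 223 and 34 without inhibitor replicates 1 and 2, Cxcl3 and Cd163 among them each time, and DESeq2 called 222. With clusters 5 and 7 added, or with the list genes used in clustering, edgeR called 0 genes.

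In Gpnmb/Spp1-like macrophages 84 genes were higher and 10 lower under the inhibitor, of 9543. Cxcl3 rose from 2.56 ± 2.92 to 88.6 ± 41.6 CPM (SD, n = 2; log2 fold change 4.88 (SE 0.51), adjusted p = 2.9e-04), and the T cell chemokine Ccl5 rose by 2.83 (SE 0.55). The acute-phase proteins Saa3 (4.00 (SE 0.83)) and Hp, or haptoglobin (2.80 (SE 0.45)), the protease inhibitor Slpi (2.96 (SE 0.43)) and the fungal lectin receptor Clec4n (3.05 (SE 0.37)) rose as well. So did H2-M2, a nonclassical MHC gene (4.69 (SE 0.48)), Cdkn1c, a cell cycle inhibitor (4.16 (SE 0.80)), and Ly6a (3.67 (SE 0.79)). Ctsk rose from 98.8 ± 29.1 to 586 ± 200.5 CPM (adjusted p = 0.00129) and Mfge8, a bridge for the uptake of dying cells, from 145 ± 1.44 to 774 ± 40.1 CPM (adjusted p = 7.5e-04). Resident macrophage markers fell in 3 of 5 cases, Folr2 (-2.20 (SE 0.36)), Cbr2 (-2.0 (SE 0.31)) and the clotting factor subunit F13a1 (-1.40 (SE 0.31)), with camera adjusted p = 1.3e-17, and adjusted p = 0.206 with an estimated correlation. The chemokine Pf4 (-2.34 (SE 0.45)) and the scavenger receptor Stab1 (-1.16 (SE 0.24)) fell as well. Both also fell in B cells, where free RNA may carry them (-4.74 (SE 0.78) and -4.43 (SE 0.81)). Free RNA from other cells was not tested as a source of the changes in these macrophages. Ly6c2 rose by 1.62 (SE 0.29). Csf1r (0.24 (SE 0.25)), Gpnmb (0.56 (SE 0.28)) and Spp1 (-0.56 (SE 0.30)) were not called. The inhibitor mice differed in several of these genes, with 6.05 and 85.4 CPM of Saa3, 8.40 and 98.8 CPM of Cdkn1c, 21.2 and 171 CPM of Ly6a, 38.0 and 206 CPM of Ccl5 and 34.9 and 130.5 CPM of Hp in replicates 1 and 2. Replicate 2 also had the larger share of T cells. Without inhibitor replicate 2, log2 fold changes were 1.26 for Saa3, 1.63 for Cdkn1c, 1.59 for Ly6a, 1.21 for Ccl5 and 1.64 for Hp, none of them called, and Cxcl3, H2-M2, Clec4n, Mfge8 and Igha were among the 6 called genes.

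By list, inflammatory cytokines rose in 4 of 17 cases over all genes and 10 adjusted over the list alone, with 3 falling on that adjustment. Examples were Il1a (2.65 (SE 0.53)), Il1b (1.89 (SE 0.31)) and the neutrophil chemokine Cxcl1 (2.19 (SE 0.34)), and camera gave adjusted p = 2.2e-11, and adjusted p = 0.267 with an estimated correlation. Interferon-stimulated genes rose in 2 of 20 and in 12 on the list's own adjustment, such as Gbp2 (2.54 (SE 0.52)) and Rsad2 (1.24 (SE 0.24)), with camera adjusted p = 1.2e-16, and adjusted p = 0.267 with an estimated correlation. Matrix genes rose in 2 of 13 (5 alone), the collagenase Mmp14 (1.6 (SE 0.25)) and the matrix protease Mmp19 (1.39 (SE 0.24)), with camera adjusted p = 1.1e-06, and adjusted p = 0.267 with an estimated correlation. NRF2 antioxidant genes rose in 2 of 14 (7 alone), the cystine transporter Slc7a11 (2.19 (SE 0.36)) and sulfiredoxin Srxn1 (1.32 (SE 0.28)), with camera adjusted p = 1.3e-07, and adjusted p = 0.281 with an estimated correlation. Cholesterol genes rose in 2 of 17 (4 alone), such as the synthesis enzyme Sqle (2.02 (SE 0.34)), with camera adjusted p = 0.00199, and adjusted p = 0.356 with an estimated correlation. Of the complement list 3 of 9 rose, Cfb (2.81 (SE 0.59)), C3 (1.85 (SE 0.41)) and Itgax (1.19 (SE 0.24)), while its camera test was not called (adjusted p = 0.056). T cell markers rose in 1 of 3 and T cell effector genes in 2 of 7, which include Ccl5 and the cytotoxic granule gene Nkg7 (2.82 (SE 0.44)), beside all of these lists. The plasma cell genes Jchain (3.69 (SE 0.63)) and Sdc1 (1.28 (SE 0.28)) and the antibody genes Igkc (4.33 (SE 0.96)) and Igha (2.25 (SE 0.44)), named after their values were seen, rose too, and plasma cells were 0.116% and 0.662% of CD45+ cells under control diet and inhibitor. Without inhibitor replicate 2 Igkc turned to -0.15, and Jchain (2.38) and Sdc1 (1.00) were not called, and without inhibitor replicate 1 Igha (1.23) and Sdc1 (1.58) were not called. Myofibre markers rose in 1 of 5 (4 alone), with camera adjusted p = 6.5e-07, and adjusted p = 0.206 with an estimated correlation. Without control replicate 1 or 2 the test called 203 or 227 genes, and without inhibitor replicate 2, whose class held 115 cells, it called 6.

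**Figure D2:**
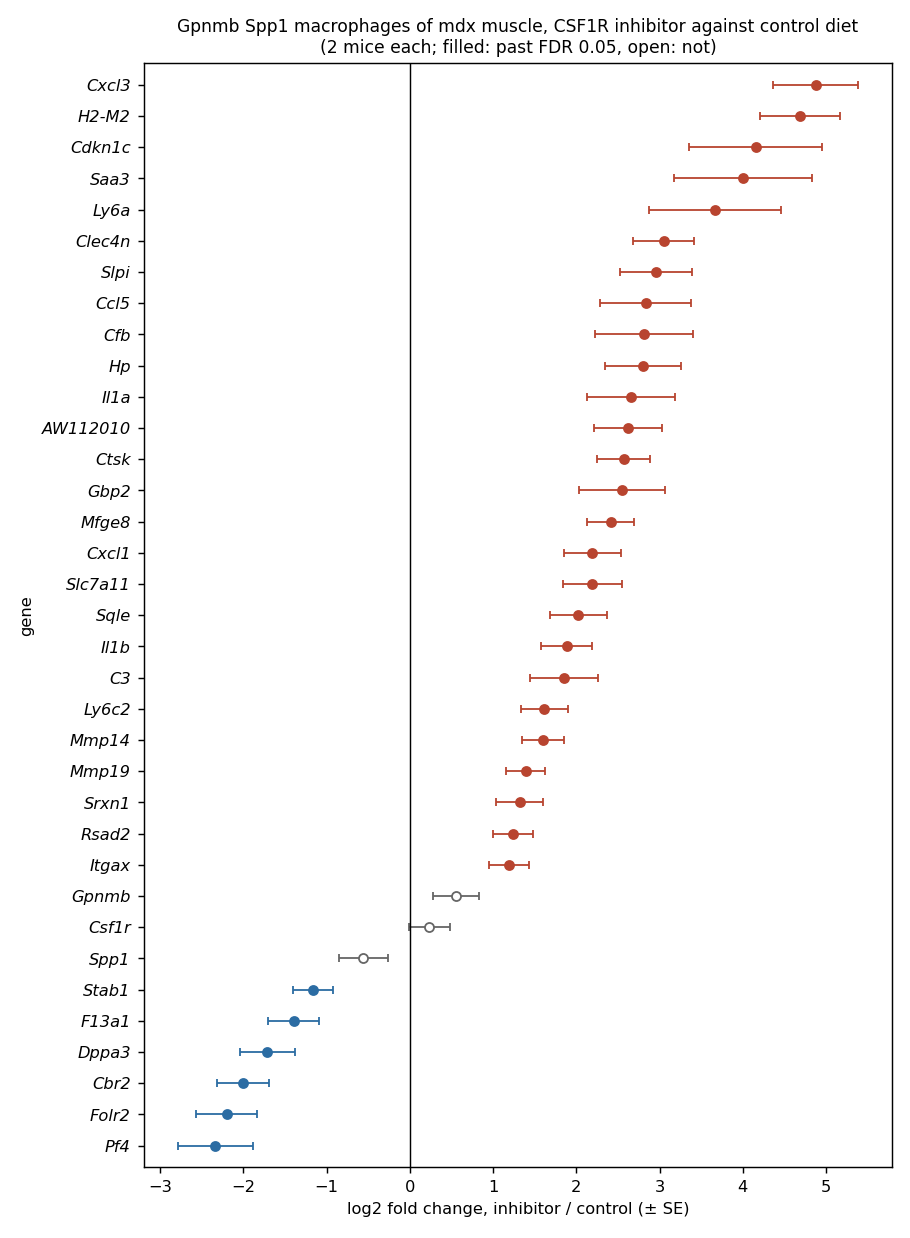
Log2 fold change, inhibitor over control diet, of named genes in Gpnmb/Spp1-like macrophages of 2 against 2 mdx mice; points are edgeR estimates, error bars SE, filled where the adjusted p was under the threshold of 0.05. Cxcl3 lies highest at 4.88 and Pf4 lowest at -2.34, and Csf1r, Gpnmb and Spp1 are open points.

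In macrophages of no special class Ccl5 (3.03 (SE 0.42)), Mmp14 (1.62 (SE 0.23)) and Traf1 (1.68 (SE 0.25)) rose, and Folr2 (-2.33 (SE 0.30)), the tetraspanin Cd81 (-2.15 (SE 0.28)), Igfbp4 (-1.97 (SE 0.30)) and F13a1 (-1.66 (SE 0.25)) fell, among 7 genes up and 4 down of 9685. Outside resident-like cells as a whole, 4 genes rose, Cxcl3, Slpi (3.02 (SE 0.38)), Ctsk (2.54 (SE 0.30)) and Mfge8 (2.01 (SE 0.25)). In mature dendritic cells 9 genes rose and 2 fell. The interferon regulator Irf7 rose from 14.0 ± 3.76 to 244 ± 83.5 CPM, Isg15 from 179.5 ± 74.8 to 983 ± 273 CPM, and the T cell priming cytokine subunit Il12b by 2.30 (SE 0.42), while Aldh1a2, which makes retinoic acid, fell by 2.70 on the log2 scale. Sct had no UMI in the control mature dendritic cells and was at least 36.4-fold higher under the inhibitor. Sct and Irf7 are also genes of plasmacytoid dendritic cells, whose share was 0.525% under control diet and 1.66% under the inhibitor, and Sct went from 0 to 54 UMIs in macrophages and monocytes as well. Type 2 innate lymphoid cells raised Ifit1 (4.13 (SE 0.66)), Rsad2 (3.00 (SE 0.51)) and Ccl5 (3.67 (SE 0.63)), and gamma delta T cells raised Ly6a (2.71 (SE 0.52)). In B cells Ly6c2 rose (2.82 (SE 0.45)) and 6 genes fell, most of them macrophage genes such as Pf4 (-4.74 (SE 0.78)) and Ccl8, at least 42.4-fold lower. Macrophage markers in these B cells fell in 5 of 9 cases adjusted over the list alone (camera adjusted p = 9.0e-11, and adjusted p = 0.216 with an estimated correlation). Cluster 5 raised 27 genes and lowered 1 of 8189, among them Cxcl1 (4.71 (SE 0.55)) and the chemokine Ccl22 (3.65 (SE 0.58)). It held 338 and 648 control cells but 277 and only 28 inhibitor cells in replicates 1 and 2.

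The interferon list was higher under the inhibitor by camera in 10 of the 12 named classes that measured it, with a positive median in all 12, across the same 4 mice. With an estimated correlation 0 classes were called (lowest adjusted p = 0.144), and fry, which asks whether a list moves one way, called 0 (lowest adjusted p = 0.0775). Without control replicate 1 or 2, fry called 1 class each time (lowest adjusted p = 0.0394 and 0.0305), and without inhibitor replicate 1 or 2 it called 0. EdgeR called 0 genes in T cells (168 at an unadjusted p under 0.05, DESeq2 1), regulatory T cells (259, DESeq2 0), NK cells (248, DESeq2 3), type 1 dendritic cells (286, DESeq2 11), type 2 dendritic cells (288, DESeq2 4), neutrophils (26, DESeq2 0) and classical monocytes (407, DESeq2 26). The smallest p-values there belonged to Pf4 and Ifit2 (2.81 (SE 0.49)) in T cells, the replication gene Hells (-3.00 (SE 0.48)) in regulatory T cells, the adhesion gene Cdh1 (3.47 (SE 0.57)) in NK cells, and Cxcl10 (4.01 (SE 0.50), adjusted p = 0.0501) in type 1 dendritic cells. In classical monocytes they belonged to Irg1 (3.55 (SE 0.43)), the itaconate-making enzyme, Mmp14 (2.70 (SE 0.34)) and the fatty acid receptor Cd36 (-2.30 (SE 0.30)), with adjusted p = 0.0622. Leaving out 1 mouse moved most of these counts. Without control replicates 1 and 2 and inhibitor replicates 1 and 2 in turn, macrophages had 267, 98, 142 and 75 called genes, mature dendritic cells 59, 47, 42 and 22, B cells 124, 7, 122 and 14, innate lymphoid cells 43, 7, 8 and 7, gamma delta T cells 21, 4, 3 and 6, and classical monocytes 20, 260, 67 and 4.

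Between 3 h and 8 h after muscle damage, wild-type macrophages and monocytes raised hypoxia, glycolysis and cholesterol genes and lowered interferon-stimulated, NRF2 antioxidant and MHC class II genes. Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050) rose from 547 ± 90.2 to 6158 ± 166 CPM (SD, n = 2 samples; log2 fold change 3.49 (SE 0.15), adjusted p = 8.0e-05). Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), the arginase of repair macrophages, rose from 111 ± 10.5 to 849 ± 165 CPM. Vegfa, an angiogenic factor, rose by 2.50 (SE 0.12), the desaturase Scd2 by 3.20 (SE 0.31) and the podoplanin gene Pdpn by 2.22 (SE 0.16). Ch25h (ENSMUSG00000050370, chromosome 19, 34473778 to 34475164), cholesterol 25-hydroxylase, fell from 279.9 ± 15.8 to 13.6 ± 6.78 CPM (-4.37 (SE 0.29)). The growth arrest gene Gadd45a (-2.64 (SE 0.16)), Serpinb2 (-2.60 (SE 0.17)), the neuropeptide receptor component Ramp1 (-3.19 (SE 0.22)) and Plac8 (-2.41 (SE 0.15)) also fell. EdgeR called 1583 genes up and 1966 down of 11255.

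Hypoxia genes rose in 11 of 15 cases and fell in none, such as Ankrd37 (2.86 (SE 0.23)) and Pdk1 (1.32 (SE 0.25)), with camera adjusted p = 2.8e-08, and adjusted p = 0.31 with an estimated correlation. Glycolysis genes rose in 9 of 17, among them the lactate exporter Slc16a3 (1.75 (SE 0.09)) (camera adjusted p = 5.0e-05, and adjusted p = 0.31 with an estimated correlation). Cholesterol genes rose in 8 and fell in 2 of 17, such as the synthesis enzymes Sqle (2.31 (SE 0.13)) and Hmgcs1 (1.81 (SE 0.15)), with camera adjusted p = 1.5e-06, and adjusted p = 0.32 with an estimated correlation. The synthesis enzymes Fdps (3.06 (SE 0.18)) and Fdft1 (2.23 (SE 0.14)), outside the list, rose as well. Matrix genes rose in 7 and fell in 4 of 15, with Timp1 (2.06 (SE 0.14)), Tgfbi (1.59 (SE 0.14)) and Thbs1 (1.56 (SE 0.12)) rising (camera adjusted p = 0.0238, and adjusted p = 0.32 with an estimated correlation). Interferon-stimulated genes fell in 13 of 21, such as Cxcl10 (-2.53 (SE 0.33)) and Gbp3 (-2.37 (SE 0.20)), with camera adjusted p = 9.6e-07, and adjusted p = 0.32 with an estimated correlation. NRF2 antioxidant genes fell in 10 of 14, such as Gclm (-1.66 (SE 0.12)) and Mgst1 (-2.21 (SE 0.17)), with camera adjusted p = 1.6e-09, and adjusted p = 0.31 with an estimated correlation. MHC class II genes fell in 7 of 12, H2-Eb1 by -1.50 (SE 0.23) (camera adjusted p = 0.00177, and adjusted p = 0.595 with an estimated correlation). Iron and haem genes fell in 5 of 12, among them the haem oxygenase Hmox1 (-1.76 (SE 0.11)) and the iron exporter Slc40a1 (-2.20 (SE 0.15)), with camera adjusted p = 2.6e-04, and adjusted p = 0.31 with an estimated correlation. Immediate early and stress genes fell in 10 and rose in 2 of 20 (camera adjusted p = 0.00252, and adjusted p = 0.595 with an estimated correlation). CSF1R axis genes fell in 7 of 11, among them the fractalkine receptor Cx3cr1 (-2.26 (SE 0.15)), with camera adjusted p = 0.00177, and adjusted p = 0.563 with an estimated correlation. Inflammatory cytokines went both ways, 5 up and 7 down of 18, with Cxcl1 up (1.50 (SE 0.22)) and Il6 (-1.87 (SE 0.34)) and Ccl12 (-2.0 (SE 0.15)) down. Adjusted over the list alone, these counts changed by at most 1 gene per direction.

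The mix of cells moved with these lists. Nonclassical monocyte markers fell in 6 of 6 cases (camera adjusted p = 3.0e-09, and adjusted p = 0.275 with an estimated correlation). Nonclassical monocytes made up 10.1% and 6.19% of cells at 3 h and 0.358% and 0.271% at 8 h. Gpnmb/Spp1-like macrophages made up 0.398% and 0.671% at 3 h and 19.7% and 22.8% at 8 h. Resident-like cells, whose share the TIM4 gate set, made up 22.7% and 26.9%, then 29.7% and 24.7%. Leaving out 3 h replicate 2 lowered the count of called genes to 1898, and leaving out 3 h replicate 1 lowered it to 2277. Over all cells of the pool, 1555 genes rose and 1868 fell of 11476, and in macrophages and monocytes other than resident-like ones 1742 rose and 2043 fell of 10594. Without 3 h replicate 2 the count over all cells was 1830, and without 3 h replicate 1 it was 2085.

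Resident-like macrophages lowered inflammatory cytokine, MHC class II, NRF2 antioxidant and iron genes over the same hours. Their cells lay mostly in cluster 1 at 8 h and in clusters 4 and 13 at 3 h. Il10, an anti-inflammatory cytokine, rose from 84.8 ± 20.2 to 375 ± 38.8 CPM (2.14 (SE 0.18)). The matrix protein Postn (2.97 (SE 0.29)), the crosslinking enzyme Tgm2 (2.81 (SE 0.33)), Arg1 (2.39 (SE 0.29)) and the cholesterol exporter Abcg1 (1.76 (SE 0.17)) rose too. Ch25h (-4.81 (SE 0.28)), Ltc4s, which makes leukotriene C4 (-4.0 (SE 0.22)), and the monocyte chemokines Ccl12 (-3.05 (SE 0.22)), Ccl7 (-2.20 (SE 0.26)) and Ccl2 (-2.13 (SE 0.28)) fell. Inflammatory cytokines fell in 9 of 18 cases, and in 11 adjusted over the list alone (camera adjusted p = 2.4e-06, and adjusted p = 0.476 with an estimated correlation). MHC class II genes fell in 8 of 9, such as H2-Aa (-1.87 (SE 0.16)), with camera adjusted p = 5.1e-18, and adjusted p = 0.29 with an estimated correlation. NRF2 antioxidant genes fell in 8 of 14 (camera adjusted p = 5.7e-11, and adjusted p = 0.29 with an estimated correlation) and iron and haem genes in 6 of 12 (9 alone; camera adjusted p = 3.6e-08, and adjusted p = 0.29 with an estimated correlation), Hmox1 by -2.21 (SE 0.20). Alternative activation genes went both ways, 3 up and 4 down of 15, with Arg1 up and Irf4 (-2.39 (SE 0.24)) and Cd209f (-1.88 (SE 0.20)) down (camera adjusted p = 0.848). Their own class markers fell in 7 of 10 (camera adjusted p = 3.4e-11, and adjusted p = 0.582 with an estimated correlation). EdgeR called 855 genes up and 1196 down of 9312, a 41.7% share up, and DESeq2 called 358 up and 801 down, a 30.9% share up.

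**Figure D3:**
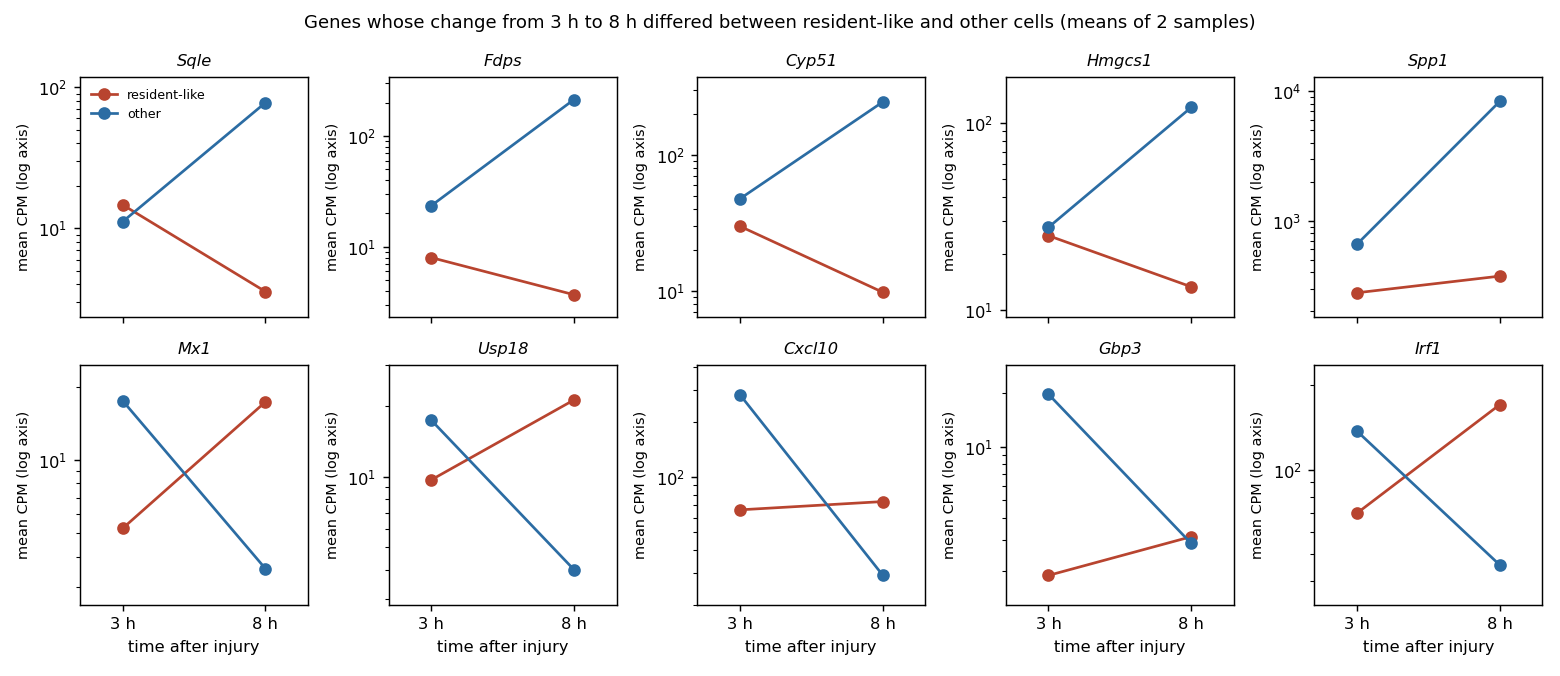
Mean CPM on a log axis at 3 h and 8 h after damage of 10 genes, 1 panel per gene, in resident-like (red) and other (blue) macrophages and monocytes; points are means of 2 tagged samples, joined by lines. Sqle went from 14.6 to 3.56 CPM in resident-like cells and from 11.2 to 77.7 CPM in the others, and Mx1 from 5.24 to 17.3 CPM and from 17.5 to 3.57 CPM.

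At 18 h after damage, macrophages and monocytes had lower antigen presentation and proliferation genes and higher inflammatory and monocyte genes than in undamaged muscle. The labels set this pool's undamaged muscle against muscle 18 h after damage. Arg1 rose from 15.4 ± 9.30 to 819.6 ± 43.5 CPM (SD, n = 2 samples; 5.89 (SE 0.28), adjusted p = 8.3e-07). The monocyte genes Ms4a4c (6.88 (SE 0.58)), Ly6c2 (5.77 (SE 0.83)), Plac8 (5.51 (SE 0.61)) and the chitinase-like Chil3 (5.84 (SE 0.25)) rose. The crosslinker Tgm2 (4.47 (SE 0.46)) and the matrix protein Thbs1 (4.34 (SE 0.21)) rose as well. Retnla (ENSMUSG00000061100, chromosome 16, 48842551 to 48844461), a mark of alternatively activated macrophages, fell by 5.63 (SE 0.35) on the log2 scale, as did Lyz1 (-6.64 (SE 0.25)) and Ear2 (-5.89 (SE 0.21)). Mki67, a proliferation marker, fell by 5.43 (SE 0.52). EdgeR called 913 genes up and 1031 down of 6501. Cells came from different clusters at the 2 states, resident-like cells from cluster 0 when undamaged and cluster 1 at 18 h, and other macrophages from clusters 5 and 6.

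MHC class II genes fell in 7 of 10 cases, H2-Eb1 by -3.53 (SE 0.27) and H2-Ab1 by -3.35 (SE 0.28), with camera adjusted p = 4.5e-17, and adjusted p = 0.263 with an estimated correlation. Proliferation genes fell in 9 of 13 (camera adjusted p = 7.8e-10, and adjusted p = 0.263 with an estimated correlation). Immediate early and stress genes fell in 16 of 20, such as the heat shock gene Hspa1a (-3.29 (SE 0.17)), with camera adjusted p = 1.2e-13, and adjusted p = 0.263 with an estimated correlation. Alternative activation genes fell in 9 and rose in 3 of 13, Mgl2 falling (-4.09 (SE 0.20)) and Arg1 rising (camera adjusted p = 2.3e-07, and adjusted p = 0.461 with an estimated correlation). Inflammatory cytokines rose in 13 of 17, such as Cxcl3 (4.46 (SE 0.41)), Ccl12 (3.84 (SE 0.30)) and Ccl2 (3.17 (SE 0.28)), while Il6 fell (-4.61 (SE 0.70)), with camera adjusted p = 2.5e-11, and adjusted p = 0.263 with an estimated correlation. Interferon-stimulated genes rose in 9 of 17, such as Irf7 (3.61 (SE 0.72)), with camera adjusted p = 6.7e-04, and adjusted p = 0.515 with an estimated correlation. Lipid-associated genes rose in 11 of 19, the fatty acid carrier Fabp4 by 4.23 (SE 0.34) (camera adjusted p = 6.3e-09, and adjusted p = 0.427 with an estimated correlation). Phagocytosis receptors rose in 9 of 16, the scavenger receptor Msr1 by 3.71 (SE 0.21) (camera adjusted p = 0.00221, and adjusted p = 0.461 with an estimated correlation). NRF2 antioxidant genes rose in 9 of 14, Slc7a11 by 2.89 (SE 0.44) (camera adjusted p = 2.8e-04, and adjusted p = 0.263 with an estimated correlation), and glycolysis genes in 9 of 17, the glucose transporter Slc2a1 by 2.23 (SE 0.38) (camera adjusted p = 0.0103, and adjusted p = 0.505 with an estimated correlation). Adjusted over the list alone, these counts changed by at most 1 gene, apart from 3 phagocytosis receptors that fell on that adjustment. Classical monocyte markers rose in 4 of 5 and resident markers fell in 8 of 9 beside them. Classical monocytes made up 26.7% and 26.8% of tagged F4/80+ cells at 18 h and 0 and 0.985% of undamaged ones. The low-count filter of at least 1 count shifted the median log2 fold change by 0.20, and 1345 genes were then up and 983 down, 57.8% up against 47.0%. A tag minimum of 1 UMI called 3578 genes, and DESeq2 called 1005.

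**Figure D4:**
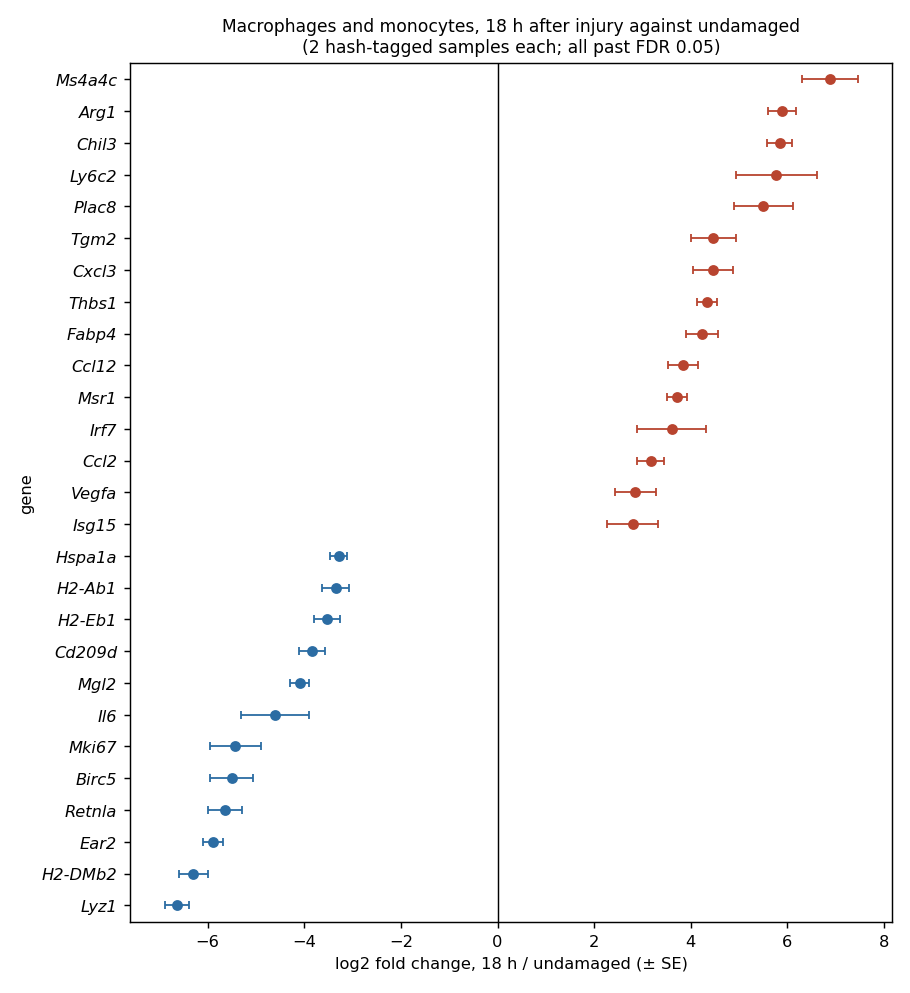
Log2 fold change, 18 h after damage over undamaged muscle, of named genes in macrophages and monocytes of 2 against 2 tagged samples; points are edgeR estimates and error bars SE. Ms4a4c (6.88) lies far above 0 and Lyz1 (-6.64) far below.

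Resident-like macrophages, which were present in undamaged muscle, differed too at 18 h. The class held 42 and 58 undamaged cells and 65 and 238 cells at 18 h. Most of its undamaged cells lay in cluster 0, and 100% and 94.5% of its 18 h cells in cluster 1. Of the 1239 cells of cluster 0, only 35 and 52 were tagged as undamaged and 0 and 10 as 18 h. Of the 718 cells of cluster 1, 1 and 1 were tagged as undamaged and 65 and 225 as 18 h. The undamaged profile thus rests on a small tagged part of cluster 0. The 10 leading genes of cluster 1 held 0 markers of the class. A change within cells is thus not separated from a change of cells. Ccl12 (4.08 (SE 0.29)), Ccl8 (2.01 (SE 0.23)) and Cxcl1 (1.98 (SE 0.27)), chemokines for monocytes and neutrophils, rose. Ptgs2, the inducible prostaglandin synthase, had no UMI in undamaged resident-like cells and was at least 12-fold higher at 18 h. The IL-4 receptor chain Il4ra (2.32 (SE 0.27)) and Hmox1 (1.35 (SE 0.31)) rose. H2-DMa (-3.73 (SE 0.27)), H2-Eb1 (-3.19 (SE 0.25)), the invariant chain Cd74 (-3.16 (SE 0.28)), Retnla (-3.50 (SE 0.36)), Mgl2 (-2.62 (SE 0.22)) and the lipid carrier Apoe (-2.86 (SE 0.38)) fell. All 8 measured MHC class II genes fell (camera adjusted p = 5.9e-20, and adjusted p = 0.43 with an estimated correlation), 11 of 15 inflammatory cytokines rose (camera adjusted p = 1.4e-08, and adjusted p = 0.536 with an estimated correlation) and 5 of 6 interferon-stimulated genes rose, Irf7 by 2.85 (SE 0.56) (camera adjusted p = 0.0075, and adjusted p = 0.641 with an estimated correlation). Proliferation genes fell in 5 of 7 (camera adjusted p = 1.9e-05, and adjusted p = 0.536 with an estimated correlation), Mki67 being 62.2-fold (95% counting interval 10.5 to 2528) lower. Of 2758 genes tested 343 rose and 416 fell. DESeq2 called 243, a tag minimum of 1 UMI gave 1735, and without undamaged replicate 2 the count was 444. Over all tagged cells 1230 genes rose and 1423 fell of 7275, and in macrophages and monocytes other than resident-like ones 747 rose and 787 fell of 5427.

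Within samples, resident-like macrophages were set apart from other macrophages and monocytes by higher alternative activation, iron and complement genes and by lower oxidative phosphorylation and glycolysis genes. The comparison spanned 11 samples with both classes, and its lists took no part in making the clusters. These were the 2 control-diet mdx mice, the parabiosis library as 1 sample over all its times, and the 4 tagged samples of each pool. The labels do not say that the tagged samples came from separate animals. The inhibitor mice held too few resident-like cells (2 and 0) to enter. Alternative activation genes were higher in resident-like cells in 11 of 15 cases (median 2.20), among them the lectins Cd209f (6.72 (SE 0.48)), Cd209g (6.72 (SE 0.44)) and Cd209d (4.89 (SE 0.54)). The list was called by camera (adjusted p = 3.4e-14) and also with an estimated correlation (adjusted p = 0.0186). Iron and haem genes were higher in 7 of 12, the exporter Slc40a1 by 4.32 (SE 0.48), the transferrin receptor Tfrc by 2.15 (SE 0.20) and Hmox1 by 1.99 (SE 0.32) (camera adjusted p = 0.00242, and adjusted p = 0.277 with an estimated correlation). Complement genes were higher in 5 of 11, C4b (ENSMUSG00000073418, chromosome 17, 34728380 to 34743882) by 4.56 (SE 0.37), while C3 was lower (-3.64 (SE 0.48)), with camera adjusted p = 5.3e-04, and adjusted p = 0.155 with an estimated correlation. Growth factor genes were higher in 6 of 14, Bmp2 by 5.19 (SE 0.27) (higher in 10 of 11 samples) and Igfbp4 by 3.21 (SE 0.27) (11 of 11), while Vegfa was lower, with camera adjusted p = 0.00242, and adjusted p = 0.251 with an estimated correlation. Oxidative phosphorylation genes were lower in 32 of 34, such as Atp5d (-1.16 (SE 0.15)) and Ndufa1 (-1.04 (SE 0.13)), with camera adjusted p = 2.5e-12, and adjusted p = 0.172 with an estimated correlation. Glycolysis genes were lower in 13 of 17, Eno1 by -1.91 (SE 0.25) and Gapdh by -1.35 (SE 0.19) (camera adjusted p = 2.2e-07, and adjusted p = 0.172 with an estimated correlation). Hypoxia genes were lower in 9 of 15, Vegfa by -3.23 (SE 0.33) (camera adjusted p = 0.0018, and adjusted p = 0.277 with an estimated correlation). Interferon-stimulated genes were lower in 7 of 20 (camera adjusted p = 0.0332, and adjusted p = 0.556 with an estimated correlation), and lipid-associated genes in 7 of 18 (camera adjusted p = 0.024, and adjusted p = 0.462 with an estimated correlation). Immediate early genes were higher in 10 of 20 (camera adjusted p = 0.0307, and adjusted p = 0.416 with an estimated correlation). Phagocytosis receptors went both ways, 5 higher and 9 lower of 21, with Stab1 (1.97 (SE 0.33), 11 of 11 samples) and Marco (2.73 (SE 0.78), 5 of 11, at means of 1.14 against 0.178 CPM) higher and Trem1 (-4.67 (SE 0.30)) and Havcr2 (-2.50 (SE 0.23)) lower (camera adjusted p = 0.0481, and adjusted p = 0.277 with an estimated correlation). The cytokine Il1b was lower (-2.34 (SE 0.28)), and the chemokine Ccl8 higher (3.48 (SE 0.43), 11 of 11 samples). Adjusted over the list alone the counts moved by at most 1 gene.

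In all, 1821 genes were higher and 2449 lower in resident-like cells of 11287 tested, 42.6% up. With DESeq2 size factors 2259 were higher and 2010 lower, 52.9% up. Genes outside the lists took part in defining the clusters, so their differences are not independent of the classes. Examples were the endothelin receptor Ednrb (4.00 (SE 0.38)) and the monoamine oxidase Maoa (3.78 (SE 0.31)) among the higher ones and the receptor Sirpb1c (-5.38 (SE 0.50)) and the leukotriene receptor Ltb4r1 (-3.88 (SE 0.42)) among the lower ones. Without the sample block 2198 genes were called, in the control-diet mdx mice only 2415, and after thinning to 1000 UMIs 2423.

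The wild-type libraries differed in sort and in time after injury, so their class shares are given as values with exact 95% intervals for counting error. Resident-like macrophages were 14.0% (12.9 to 15.1) of the parabiosis library, whose sort was spiked with TIM4+ cells, 40.7% (39.3 to 42.1) of the F4/80+ pool and 25.9% (25.0 to 26.9) of the TIM4-balanced pool. All macrophages and monocytes were 89.3%, 81.8% and 88.7% of these libraries. Gpnmb/Spp1-like macrophages were 22.5%, 9.43% and 11%. In the 18 h pool they were 13.8% and 16.3% of damaged samples and 0 of 107 and 0 of 203 undamaged cells, which allows up to 2.80% and 1.48%. An unnamed cluster led by Ppbp, Pf4 and Cxcl3 held 22.0% and 24.7% of 18 h cells and 0.935% and 0.985% of undamaged ones. Type 2 dendritic cells were 19.6% and 28.6% of undamaged cells and 0.431% and 0 of 1155 at 18 h. The shares by state are of tagged cells, and tags were assigned unevenly between clusters.

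**Figure D5:**
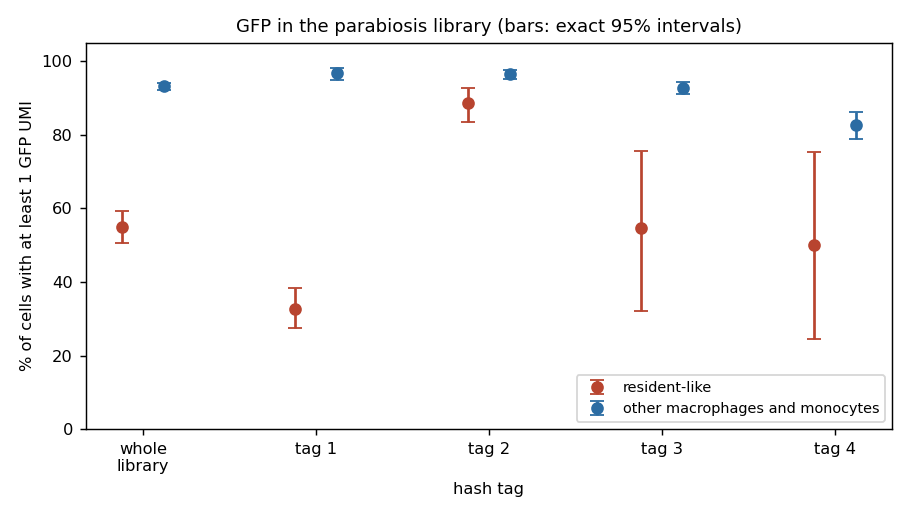
Share of cells (%) with at least 1 GFP UMI among resident-like and other macrophages and monocytes of the parabiosis library, for all cells and by hash tag; points are shares and error bars exact 95% intervals for counting error, 1 library. Over all cells the shares are 55.1% and 93.2%.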

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

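The tests of whether a change with time differed between resident-like and other macrophages and monocytes were chosen after the changes in each class had been seen. They used edgeR on the summed counts of the same tagged samples, with the sample in the model.

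Between 3 h and 8 h after damage, cholesterol and interferon-stimulated genes changed differently in resident-like macrophages and in the other macrophages and monocytes. The change differed for 2912 of 10927 genes, 1330 of them higher and 1582 lower in resident-like cells, which makes this a difference between groups. Sqle, an enzyme of cholesterol synthesis, went from 14.6 to 3.56 CPM in resident-like cells and from 11.2 to 77.7 CPM in the others (difference in log2 fold change -4.85). Of the synthesis enzymes outside the list, Fdps went from 8.00 to 3.70 CPM and from 23.6 to 213.6 CPM (-4.27), and Cyp51 (-3.98) and Idi1 (-3.70) differed in the same direction, as did the list member Hmgcs1 (-3.02). Of 17 cholesterol genes 10 were lower and 3 higher (camera adjusted p = 0.00116, and adjusted p = 0.545 with an estimated correlation). Spp1 went from 278 to 374 CPM in resident-like cells and from 659 to 8308 CPM in the others (-3.27). Interferon-stimulated genes were higher in 17 of 20 cases and lower in 0 (median 2.27; camera adjusted p = 1.2e-11, and adjusted p = 0.545 with an estimated correlation). Mx1, an antiviral GTPase, went from 5.24 to 17.3 CPM in resident-like cells and from 17.5 to 3.57 CPM in the others (3.90). Cxcl10 went from 66.2 to 73.5 CPM and from 283 to 29.1 CPM (3.26), and Gbp3 (3.50) and Usp18 (3.20) were also higher. Irf1 (2.88), outside that list, and the cholesterol exporter Abcg1 (3.53) were higher as well. Immediate early and stress genes were higher in 14 and lower in 2 of 20 (camera adjusted p = 2.1e-07, and adjusted p = 0.545 with an estimated correlation). Hypoxia genes were lower in 7 of 15 (camera adjusted p = 8.8e-04, and adjusted p = 0.545 with an estimated correlation). Without 8 h replicate 2 the test called 1271 genes and without 8 h replicate 1 it called 1497. On simulated counts it recovered 82% of 4-fold differences. The other cells were not the same mix at both times. Of their classical monocytes 68.0% and 56.2% lay in cluster 0 at 8 h and 3.00% and 0.986% at 3 h, when clusters 2, 6 and 7 held most of them. Cluster 0 took that name by its score, with 0 markers of the class among its 10 leading genes. Of all tagged cells, Gpnmb/Spp1-like macrophages were 0.398% and 0.671% at 3 h and 19.7% and 22.8% at 8 h, and nonclassical monocytes 10.1% and 6.19% and then 0.358% and 0.271%. Resident-like cells too lay in different clusters, 99.3% and 99.1% in cluster 1 at 8 h and 87.1% and 87.7% in cluster 4 at 3 h. The test does not separate a change of mix from a change within cells.

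Between undamaged muscle and 18 h after damage the change differed for 437 of 5036 genes, 188 higher and 249 lower in resident-like cells. Apoe, a lipid carrier, went from 19471 to 2636 CPM in resident-like cells and from 2582 to 2651 CPM in the others (-3.00). Spp1 went from 532 to 349 CPM and from 213 to 7617 CPM (-5.36), and the lectin receptor Clec4n from 215 to 59.1 CPM and from 24.7 to 671 CPM (-6.13). Thbs1 (-2.74) and the monocyte gene Plac8 (-6.16) were lower as well. Areg, a growth factor for muscle repair, went from 9.20 to 61.0 CPM in resident-like cells and from 101 to 35.4 CPM in the others (4.20), and Il6 from 56.7 to 14.6 CPM and from 327 to 7.11 CPM (4.17). Lipid-associated genes were lower in 9 and higher in 1 of 19 (camera adjusted p = 3.1e-08), CSF1R axis genes lower in 5 of 8 (camera adjusted p = 2.9e-05), complement genes lower in 4 of 8 (camera adjusted p = 0.00169) and immediate early genes higher in 7 and lower in 1 of 20 (camera adjusted p = 2.9e-05). With an estimated correlation each of these 4 lists had adjusted p = 0.314. Without undamaged replicate 2 the test called 255 genes and without 18 h replicate 2 it called 274. On simulated counts it recovered 58% of 4-fold differences. The other cells were not the same mix in both states. Gpnmb/Spp1-like macrophages were 0 and 0 cells when undamaged and 32 and 188 at 18 h. Classical monocytes were 0 and 2 cells, then 62 and 310. Macrophages of no special class lay mostly in cluster 5 when undamaged and in cluster 6 at 18 h. Resident-like cells lay mostly in cluster 0 when undamaged and in cluster 1 at 18 h. A change of mix is not separated here from a change within cells.

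GFP transcripts of the parabiosis library took no part in the comparisons. At least 1 GFP UMI was seen in 93.2% (92.2 to 94.1) of 2818 other macrophages and monocytes and in 55.1% (50.7 to 59.4) of 523 resident-like cells, with exact 95% intervals for counting error. The sort took GFP+ cells and added TIM4+ GFP- cells, and the library held no cell type known to lack the gene. Resident-like cells had a median of 5128 UMIs and the others 12332, and after thinning the shares were 43.4% and 72.3%. By tag, GFP was seen in 32.8%, 88.7%, 54.5% and 50% of 290, 194, 22 and 16 resident-like cells of tags 1 to 4, and in 96.8%, 96.4%, 92.8% and 82.8% of the others.

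The hash tags of that library, which the labels map to no condition, also held different classes of cells. Resident-like cells made up 34.6%, 16.2%, 1.99% and 2.68% of tags 1 to 4, over 837, 1196, 1104 and 597 cells. Classical monocytes made up 52.1%, 13.5%, 1.09% and 2.35%. Gpnmb/Spp1-like macrophages made up 0 of 837 cells of tag 1, then 67.1%, 2.45% and 2.01%, and macrophages of no special class 0.597%, 2.51%, 84.2% and 63.7%. The labels list 6 h and 2, 4 and 8 days after injury for this library. Whether the tags follow these times could not be tested, because the labels do not link them. No explanation was tested for these shares.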

How the results depend on the processing

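The alternatives added after seeing the data were a tag minimum of 1 UMI, clusters 5 and 7 added to the macrophages and monocytes, DESeq2 on the separate mdx classes and on resident-like and other cells apart, and each alternative of the tests of class by time. Directions of named genes mostly held. In resident-like against other cells 1600 of 1658 values over 84 genes kept their direction and their side of the threshold, 52 lost the call and 6 turned. For macrophages and monocytes these were 749 of 799 values over 89 genes from 3 h to 8 h and 751 of 789 over 88 genes at 18 h, the rest losing the call. In mdx Gpnmb/Spp1-like macrophages 344 of 420 kept both, 63 lost and 10 gained the call, and Igkc ran from -0.15 without inhibitor replicate 2 to 5.35 without inhibitor replicate 1. In mdx macrophages and monocytes 501 of 677 kept both and 161 gained the call. Class shares kept their direction in 143 of 156 values and marker shares in 49 of 54. At Leiden resolution 0.5 no mdx cluster was named resident-like, which left that share without a value. On simulated counts the test recovered 15% of 4-fold changes in neutrophils and 55% each in B cells and regulatory T cells. The cause was not tested except where fewer samples or genes entered.

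With DESeq2 the calls numbered 601 in the whole sort, 222 in mdx macrophages and monocytes, 109 in those other than resident-like, 56 in macrophages, 26 in classical monocytes, 11 in cDC1, 4 in cDC2, 4 in B cells, 3 in NK cells, 1 in T cells, 1 in ILC2 and 0 in gamma delta T cells. At 18 h DESeq2 called 1505 genes in all cells, 1005 in macrophages and monocytes, 841 in other and 243 in resident-like cells, and 1159 in resident-like cells from 3 h to 8 h. The filter of at least 1 count, under which more genes are tested, gave 1306 in the whole sort, 545 in macrophages and monocytes, 332 in those other than resident-like, 247 in Gpnmb/Spp1-like macrophages, 210 in macrophages, 168 in classical monocytes, 116 in cDC1, 83 in B cells, 58 in mature DC, 55 in cDC2, 39 in NK cells, 23 in T cells, 16 in ILC2, 15 in neutrophils, 11 in regulatory T cells and 7 in gamma delta T cells. DESeq2 size factors gave 2 in cDC1. In mdx macrophages and monocytes Leiden resolution 0.5 gave 13 calls, clusters made with the list genes 0, kept doublets 53, thinning 62 and clusters 5 and 7 added 0. A tag minimum of 1 gave 4201, 3578, 2387 and 1735 calls at 18 h in all cells, macrophages and monocytes, other cells and resident-like cells. TMM over classes called 10 classes in the abundance model. With an estimated correlation or with fry, 0 functional lists were called in the whole sort and in macrophages and monocytes, and 0 classes had the interferon list up, but fry called 1 class without control replicate 1 or 2.

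Differences in class shares (inhibitor minus control, percentage points) became -0.115 for B cells and 0.255 for classical monocytes under the strict cell filter. For classical monocytes the difference was 0.801 at resolution 2 and 31.5 as a share of macrophages and monocytes. It was also -5.54 at resolution 0.5 and -2.20 with doublets kept. Type 2 dendritic cells went from -4.91 to -10.5 at resolution 0.5. Gpnmb/Spp1-like macrophages went from -7.69 to -16.1 at resolution 2, and their mice overlapped between diets under the strict filter. Macrophages of no special class went from -18.6 to -8.99 with doublets kept, and their mice then overlapped. Differences in marker shares became -4.32 for Gpnmb without thinning and -1.0 for Ccr2 thinned to 2000 UMIs. Resident-like cells of the parabiosis library were 17.6% at resolution 0.5, 10.7% at resolution 2, 11.5% under the strict filter and 20.2% with doublets kept. In the 18 h pool they were 29.7%, 36.6%, 35.2% and 35.8%. In the 3 h and 8 h pool they were 28.8% at resolution 0.5, 24.1% under the strict filter and 28.3% with doublets kept. All macrophages and monocytes of the parabiosis library were 86.3% at resolution 0.5, 79.4% at resolution 2 and 86.8% with doublets kept. In the 18 h pool they were 73.6% at resolution 0.5 and 87.9% with doublets kept. In the 3 h and 8 h pool they were 92.2% and 84.0% at resolutions 0.5 and 2, 90.5% under the strict filter and 91.7% with doublets kept.

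Resident-like against other cells gave 2415 calls in the control-diet mdx mice only, where fewer samples entered, and 2423 after thinning. In the control-diet mdx mice only, Irf7 (0.0442), Mcm3 (-0.47), Mcm6 (-0.33), Pcna (-0.38) and Mylip (-0.27) turned direction. Without the replicate block this comparison gave 2198 calls and Retnla turned to -0.14. From 3 h to 8 h, tags of a like number need not pair, and the differences between replicates 1 and 2 at both times correlated over genes at r = 0.0333, genes not being independent replicates. With the number as a replicate block 1546 genes rose and 1856 fell in all cells, 1667 and 2024 in macrophages and monocytes, 1163 and 1435 in resident-like cells, and 1967 and 2234 in the others.

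Leaving out each replicate in turn gave the following lowest and highest values, the lone sample of an arm being assumed to vary like the other group. Calls in the mdx mice numbered 0 to 1206 in the whole sort, 34 to 223 in macrophages and monocytes, 25 to 307 in those other than resident-like, 6 to 227 in Gpnmb/Spp1-like macrophages, 75 to 267 in macrophages, 4 to 260 in classical monocytes, 22 to 59 in mature DC, 27 to 141 in cDC1, 3 to 55 in cDC2, 7 to 124 in B cells, 7 to 43 in ILC2, 3 to 21 in gamma delta T cells, 0 to 48 in NK cells, 0 to 14 in T cells, 0 to 10 in regulatory T cells and 0 to 14 in neutrophils. The abundance model called 1 to 12 classes, and 6 to 13 functional lists were called in macrophages and monocytes. Differences in shares ran from -0.574 to 0.907 for B cells, -0.120 to 2.61 for ILC2, -0.103 to 1.77 for cDC1, -5.17 to 5.12 for classical monocytes, -0.0850 to 0.300 for mast cells and -0.678 to 4.00 for neutrophils. Differences in marker shares ran from -7.09 to 9.12 for Gpnmb and -0.0578 to 0.534 for Timd4. From 3 h to 8 h the calls were 1830 to 3557 in all cells and 1898 to 3472 in macrophages and monocytes, and at 18 h 444 to 819 in resident-like cells. The tests of class by time called 1271 to 3270 genes from 3 h to 8 h and 255 to 359 at 18 h. Those tests gave 2974 and 429 calls with DESeq2 size factors and 3271 and 333 with at least 1 count.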

Other observations

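The test of free RNA of the whole library in T cells was chosen after its values were seen. Within the macrophages and monocytes of mdx muscle, classical monocytes took a larger share under the inhibitor, with p = 0.333 by the two-sided exact permutation test, the smallest that 2 against 2 mice allow. Classical monocytes were 20.2% ± 7.03 of these cells under control diet and 51.7% ± 11.8 under the inhibitor (SD, n = 2). Macrophages of no special class were 43.6% ± 11.8 and 22.4% ± 5.19, nonclassical monocytes 1.87% ± 0.0131 and 0.475% ± 0.0930, and resident-like macrophages 7.42% ± 3.13 and 0.0511% ± 0.0723. Gpnmb/Spp1-like macrophages were 26.9% ± 7.93 and 25.4% ± 6.60, whose mice overlapped. Of all CD45+ cells, antibody-secreting plasma cells were 0.116% ± 0.125 under control diet and 0.662% ± 0.390 under the inhibitor (log2 fold change 2.59, adjusted p = 0.0503 in the edgeR model), neutrophils 2.20% ± 1.41 and 3.86% ± 3.31, mast cells 0.330% ± 0.272 and 0.437% ± 0.213, and type 2 innate lymphoid cells 1.46% ± 0.413 and 2.70% ± 1.93.

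A cluster with T cell and macrophage transcripts together held 0.987% ± 0.273 of CD45+ cells under control diet and 7.34% ± 4.07 under the inhibitor. EdgeR called 0 of 7036 genes between the diets within it, with 478 at an unadjusted p under 0.05, and DESeq2 called 22. The smallest p-values belonged to Fxyd2 (-2.70), Igfbp4 (-3.12) and the resident macrophage chemokine Pf4 (-3.15).

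For that cluster 3 technical explanations were tested, free RNA in T cells in 2 ways. Droplets that took 2 cells at random were excluded, because the inhibitor mice held at least 9.86 times the T cell with macrophage or monocyte doublets expected from loading, and the control mice 6.47 and 4.37 times. Free RNA of the whole library would raise markers of neutrophils, B cells and plasma cells over T cells about as much as macrophage markers. In the inhibitor mice those markers were 2.24 and 1.13 times as high as in T cells. This was 0.111 and 0.0345 of the ratio of macrophage markers (upper 95% counting bounds 0.149 and 0.0369). In the control mice it was 0.0584 and 0.336 (0.0978 and 0.997), the last from 6 UMIs in T cells. Picking the cluster for macrophage transcripts lowers this quotient by itself, and the test was chosen after its values were seen. In the inhibitor mice the values argue against this explanation but do not exclude it. RNA from macrophages alone stayed open, since the cluster was picked for macrophage transcripts and their CPM of at least 15.8 times that in T cells decides nothing, and so did pairs of cells that entered 1 droplet together, as the median UMIs were 1.18, 0.80, 1.07 and 1.41 times the sum of both cell types' medians, of which the last lay above the bound set beforehand. A cell state with both programs that goes with the diet also stays open and was not tested.

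A changed mix of classes and lower depth were tested on both genes called between the diets in summed macrophages and monocytes, where control class profiles mixed in each mouse's proportions gave 0.16 of the 4.45 log2 fold change of Cxcl3 and -1.23 of the -5.67 of Cd163, an upper quartile of 0.171 for predicted over observed. After thinning to equal depth, Cxcl3 kept 3.21 (SE 0.55), Cd163 had no UMI in inhibitor cells and was at least 19.1-fold lower, and the lower quartile of thinned over unthinned values was 0.926 as fitted, which has no bound, and 0.728 with Cd163 at its bound. Both genes passed the bounds singly and by more than their spread, a requirement added after the values were seen. For these 2 genes this argues against the mix of named classes as the whole cause. The test rested on 2 genes, fewer than the 10 called genes set as the minimum for testing an explanation. Thinning keeps each cell's expected composition, so summed shares move only through cell weights and cells left out. It could hardly have shown an effect of depth, so depth stays open. With clusters 5 and 7 added the log2 fold changes were 3.81 and -3.92, neither of them called (adjusted p = 0.0613 for each). An effect of the diet within cells and a change of mix within the named classes stay open and were not tested.

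Macrophage markers were also lower under the inhibitor in T, B and NK cells, in which free RNA may carry them. If free RNA were the source, their fold changes should follow those of the whole sort, and the median differences were 0.02 in T cells, -0.54 in B cells and 0.26 in NK cells, over 8, 9 and 4 markers. The largest of these, -0.541, lay just past the bound of 0.5 for this explanation and short of the bound of 1 against it. Free RNA and a change within these cells cannot be told apart, because 1 of the 3 values missed the first bound.

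Between resident-like and other macrophages and monocytes 4270 genes were called. Of 50 swaps of the classes within samples, the real one included, 1 called as many, and the highest of the others called 1662. The classes were made by clustering the same cells, which puts the real classes above the swaps by itself, so the swaps cannot tell whether chance is excluded.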
